A study of Arabidopsis thaliana with 22 samples.

How the data were processed

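Small RNAs of 18 to 28 nt were sequenced from Arabidopsis thaliana flower buds, in 22 libraries of 15 groups. Per the labels' protocols, plants grew on soil in 18 h days at 23 °C, total RNA was extracted with Trizol and enriched with the mirVana kit, RNA bound to immunoprecipitated protein was taken up in Trizol LS, and libraries were made with a TruSeq kit. The 9 total small RNA libraries are single libraries of wild-type Col, pol4 and ddm1 and pairs of ddm1-dcl3, ddm1-ago6 and ddm1-pol4-rdr6. The 9 FLAG immunoprecipitates are pairs from ago6 and ddm1-ago6 plants with the FLAGAGO6 transgene, pairs of mock precipitates from the same mutants without it, and 1 library of an ago6 FLAGAGO6 lysate to which 20 µg of ddm1 small RNA had been added. The last 4 libraries are single precipitates with an AGO6 antibody, from Col and ddm1 and, as mocks, from ago6 and ddm1-ago6. The mock plants lack both the transgene and AGO6 function, so a precipitate and its mock differ in genotype as well as in the protein recovered.

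The authors deposited, for each library, a table with the count of reads of each distinct sequence. The trimmer, the aligner and the filters behind these tables are not given in the sources used here, and the build was TAIR10 per the submitters' processing notes. The authors also deposited 6 tables over tiles of 100 bp, spaced 25 bp apart. Per the file headers, their columns give a ratio called relative enrichment for 21 to 22 nt and for 24 nt RNAs of an immunoprecipitate, and further columns give a score, the authors' RPM of total small RNA rounded to whole numbers. Of the columns, 12 were used and 12 were not. How immunoprecipitate, mock and total RNA entered the ratio is not stated there, so these values are only described, as the authors' own.

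Each of the 11270322 distinct sequences was placed by perfect match on the TAIR10 assembly in its RefSeq copy, which may differ in annotation from the one the authors used. No sequence lacked a match. A sequence was given whole to the locus that held more than 50% of its matches, and ties were left out. This placed 14.8 to 31.7% of the 21 to 22 nt reads and 21.3 to 35.7% of the 24 nt reads of a library, and the other reads lay outside the loci or had no locus with more than 50% of their matches. The unit tested was a locus in a size class, 21 to 22 nt or 24 nt. A set of 17 mature miRNA and trans-acting siRNA sequences, matched by exact sequence, made further units. The loci were grouped as 27444 protein-coding genes, 4843 pseudogenes, 326 MIR genes, 6 TAS loci, 4282 other non-coding RNAs, and tRNA, rRNA, snRNA and snoRNA genes. The annotation names no transposable element families. Transposable element genes are among its pseudogenes, which therefore stand in for the planned families, and the list is called pseudogene and TE gene loci below. Sets resembling Athila (12 loci, seed AT2G11120), the Copia element EVD (3 loci, seed AT5G17125) and AtMu1 (4 loci, seed AT4G08680), found by BLAST at 75% identity or more over at least 200 bp, were defined after the files had been seen, as was the set of 16 Sadhu loci. For shares of a library by locus type, the reads of a sequence were divided evenly over its matches.

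Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, in 1 fit for the FLAG libraries and 1 for the total RNA libraries. After filterByExpr, the FLAG fit held 8858 units (5168 of 21 to 22 nt and 3690 of 24 nt) with 4 residual degrees of freedom and a common dispersion of 0.201. The total RNA fit held 7783 units (3247 and 4536) with 3 residual degrees of freedom and a dispersion of 0.0974. Its prior degrees of freedom were infinite, against 22.7 in the FLAG fit. Its tests thus used a spread shared among units, not each unit's own. Library size was the number of nuclear reads, which came to 100% of the reads in every library at 3 digits, and scaling factors were 1. Groups with a single library, ddm1 total RNA and the spiked lysate, were assumed to vary like the others. Levels are RPM, the reads of a unit scaled by the nuclear reads of its library, with the SD over replicates, and standard errors of log2 fold changes were taken as the fold change over the square root of F. A fold against a group without a read is a lower bound, against 3 counts over that group's libraries. Lists were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Groups of 2 libraries cannot reach p under 0.333 in an exact two-sided permutation test, so shares are given with their SD and no such test is quoted. The labels do not say that replicates came from separate plants, so the p-values of the fits measure only the spread between these samples. Fisher's p-values count loci as independent and measure no spread between samples. The lists it compared were not matched for read level. Replicate pairs differed by far more than counting error, with a chi-square per unit of 11.7 to 50.7 and a Pearson correlation of log2 values across units of 0.877 to 0.952.

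Pairs of single libraries were compared without a test. Their log2 ratios were taken after adding 0.5 RPM, over units with at least 50 reads in the pair, with Poisson intervals for levels, and each list's median was placed among 10000 random lists of the same size drawn from 10 level bins. Shares in single libraries carry 95% Wilson intervals. All intervals and floors cover counting error only. The genes named were set by rule. In a tested comparison they are the 10 highest and 10 lowest log2 fold changes among called units with at least 10 RPM in the mean of 1 group or more and with every library of 1 group on the same side of every library of the other, and for the interaction both replicate differences likewise. TAS loci and mature sequences belong to the named set whether called or not, and the text gives those needed to describe a comparison. Between single libraries the 5 highest and 5 lowest ratios are named. The groups, tests, alternatives and this rule were fixed before the data were examined, except where the text says that they were added later.

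On simulated counts with 50 changed units per fold size, the test recovered, for FLAGAGO6 against mock in ago6, 0% of 2-fold, 36% of 4-fold, 50% of 8-fold and 76% of 16-fold changes. For ddm1-dcl3 against ddm1 the shares were 0, 20, 40 and 64%, and for the interaction they were 0, 4, 14 and 42%. No simulated change was called in the wrong direction, and 2 to 7 unchanged units were called per comparison. All other units had the same mean in every group, with library sizes known. The simulation therefore does not cover shifts of most units or errors of scaling, which can turn directions. The alternatives were TMM factors, library sizes set to the reads of MIR genes (miRNA scaling), DESeq2 1.42.0 with its own size factors, no low-count filter, only sequences with 1 match, each replicate left out, the replicate letter as a block, other denominators for shares, 0.1 or 2 RPM in place of 0.5 and, added after the data were seen, reads divided over all matches. Chromosome profiles used bins of 500000 bp, of which the 60 with the most pseudogene loci, at least 17.25 each, are called dense. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and BLAST 2.17.0 were also used.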

Results

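Small RNAs were counted in flower buds of wild-type Arabidopsis (Col) and of mutants. Transposable elements were taken to be silent in Col, pol4 and ago6, and transcribed where the chromatin remodeler DDM1 is missing (ddm1 and its combinations). Transcripts of the elements were not measured here. POL4 makes the precursors of 24 nt siRNAs, DCL3 cuts them, RDR6 makes the precursors of 21 to 22 nt siRNAs, and AGO6 is an Argonaute protein that carries siRNAs to chromatin in RNA-directed DNA methylation. The 9 total RNA libraries held 1.54 to 10.2 M reads, the 9 FLAG precipitates and mocks 2.37 to 11.8 M, and the 4 libraries made with an AGO6 antibody 2.69 to 17.4 M. A count of 3 reads corresponded to 0.172 to 1.94 RPM. Between 20.7 and 63.7% of the reads of a library matched the genome once. Col, pol4, ddm1, the spiked lysate and the antibody precipitates have 1 library each, and all other groups have 2.

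The targeted genes were examined in every library. Small RNAs from a gene do not measure the loss of its mRNA, so these values describe only its small RNAs. AGO6 (AT2G32940, chromosome 2, 13971916 to 13977521, TAIR10) gave abundant 21 to 22 nt RNAs in all 7 ddm1-ago6 libraries: 1533 and 1857 RPM in total RNA, 1087 and 2598 RPM in FLAG mocks, 2428 RPM in the antibody mock, and 103 and 146 RPM in the FLAGAGO6 precipitates. The 6 ago6 libraries had 1.26 to 4.72 RPM, and the 9 libraries of other genotypes 0 to 0.591 RPM. COP1 (AT2G32950, chromosome 2, 13977881 to 13983609), the neighbouring gene and a repressor of photomorphogenesis, gave 60.8 and 71.7 RPM in the ddm1-ago6 FLAGAGO6 precipitates and at most 0.885 RPM in the other 20 libraries. RDR6 (AT3G49500, chromosome 3, 18348974 to 18353673) gave 36.7 and 40.8 RPM in ddm1-pol4-rdr6 and at most 2.26 RPM in the other 20. DDM1 stayed at or under 0.396 RPM, DCL3 at or under 1.94 RPM and NRPD1, the largest subunit of POL4, at or under 2.18 RPM in the 22 libraries.

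**Figure D1:**
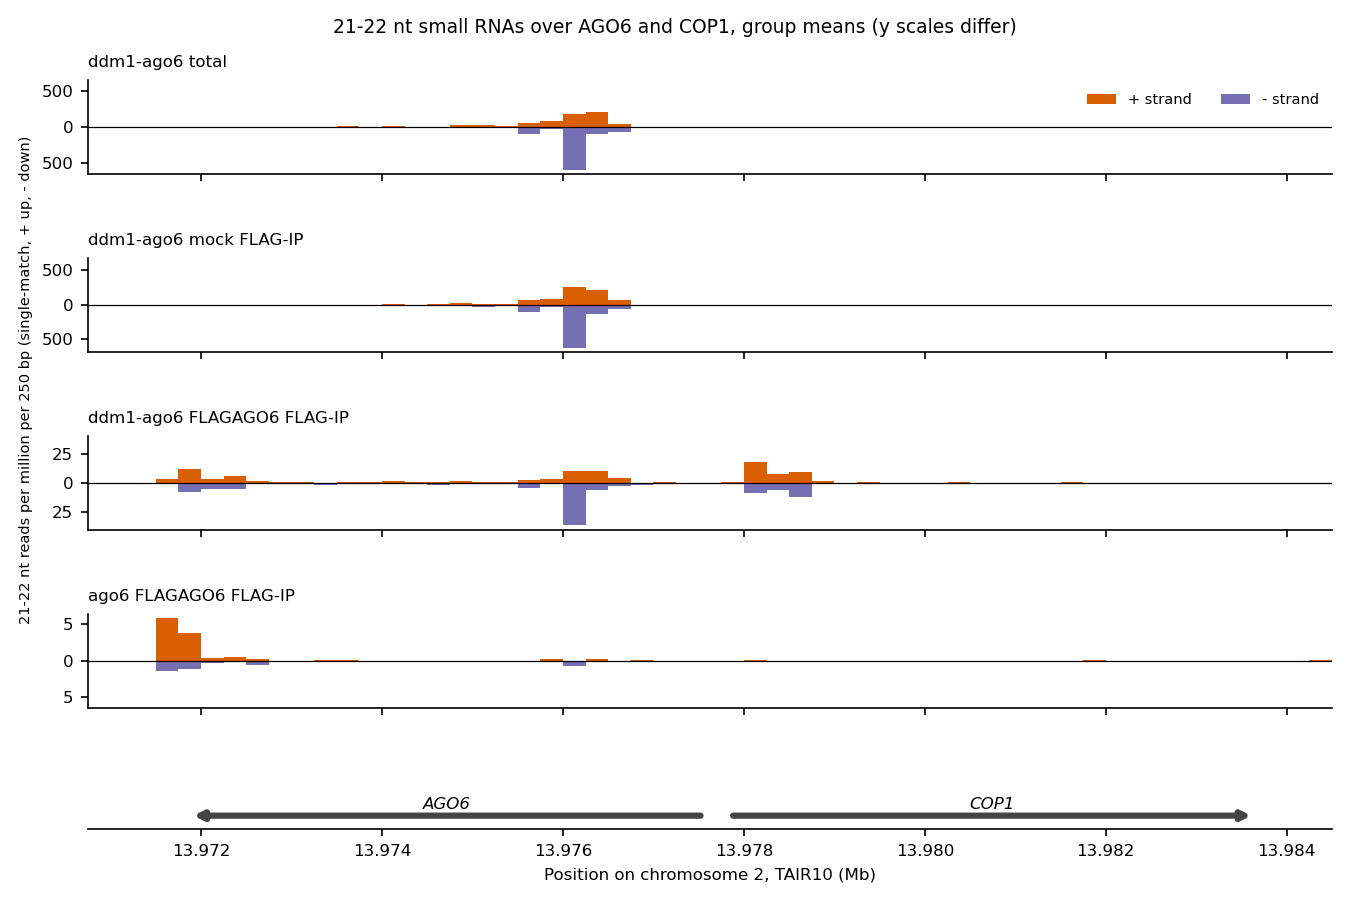
Reads of 21 to 22 nt with a single genomic match over AGO6 and COP1 on chromosome 2, in RPM per 250 bp on the plus (up) and minus (down) strand, for 4 groups with different vertical scales. Reads of ddm1-ago6 plants lie over AGO6, and COP1 has reads in the FLAGAGO6 precipitates of ddm1-ago6.

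The makeup of total small RNA was compared between genotypes to see which size classes transposable elements feed. In Col, 24 nt RNAs made up 48.3% of reads and 21 to 22 nt RNAs 33.2%. In pol4 the 24 nt share was 3.56% and the 21 to 22 nt share 74.7%, and in ddm1 they were 39.0% and 45.3%. The 24 nt share was 36.9% ± 1.15 (SD, n = 2) in ddm1-ago6, 10.4% ± 2.94 (n = 2) in ddm1-dcl3 and 7.53% ± 0.489 (n = 2) in ddm1-pol4-rdr6. RNAs of 22 nt made up 20.2% ± 1.90 in ddm1-dcl3, against 10.2% ± 0.0768 in ddm1-ago6 and 8.25% in ddm1. Of the 21 to 22 nt reads, pseudogene and TE gene loci held 3.59% in Col (Wilson 95% interval 3.56 to 3.62), 0.191% in pol4 (0.185 to 0.198) and 29% in ddm1 (28.9 to 29.1). Their share was 46.9% ± 2.23 in ddm1-ago6, 31.2% ± 2.38 in ddm1-dcl3 and 1.09% ± 0.261 in ddm1-pol4-rdr6. TAS loci, the sources of trans-acting siRNAs, held 1.16% in Col, 0.942% in ddm1 and 0.0192% ± 0.00686 in ddm1-pol4-rdr6. Within the reads of pseudogene and TE gene loci, 21 to 22 nt RNAs were 13.2% in Col (13.1 to 13.3), 64.1% in ddm1 (64.0 to 64.2), 73.9% ± 0.860 in ddm1-ago6 and 80.1% ± 4.06 in ddm1-dcl3. The replicates of ddm1-dcl3 and ddm1-ago6 did not overlap in these shares of pseudogene and TE gene loci or of 22 and 24 nt RNAs, but groups of 2 cannot reach p under 0.333 in an exact permutation test.

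**Figure D2:**
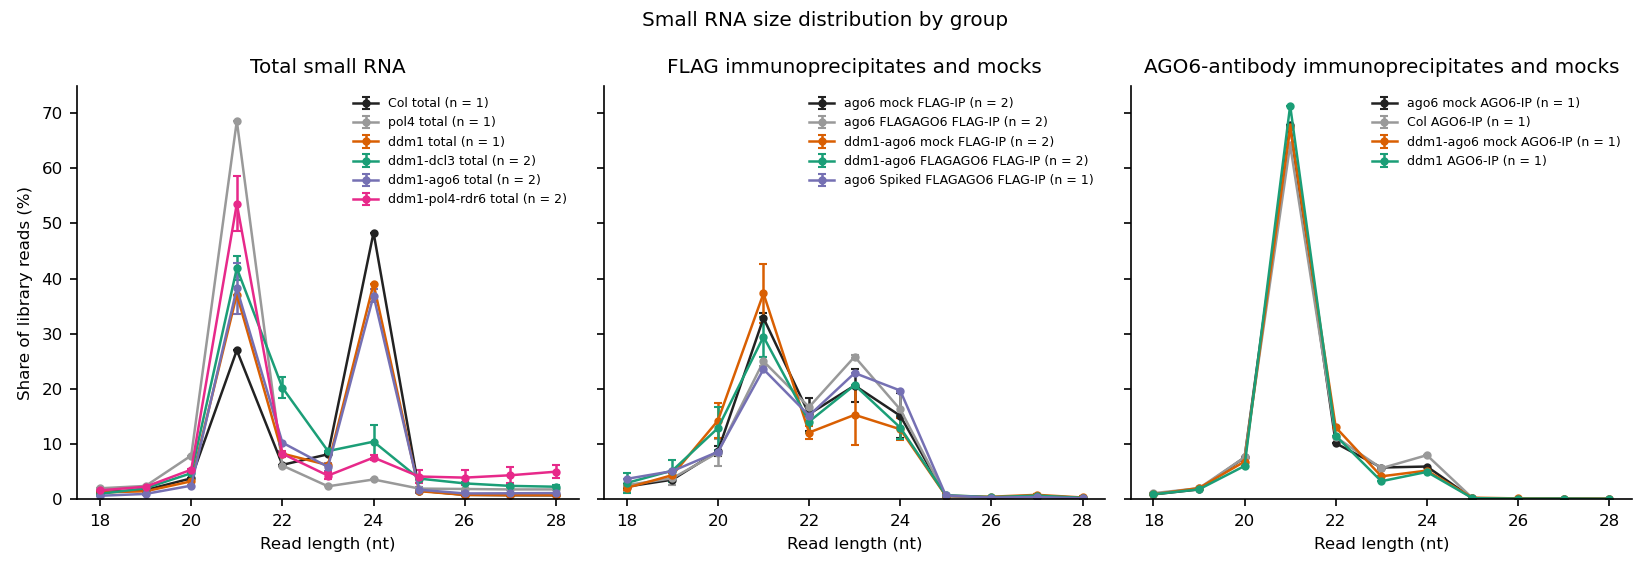
Share of reads (%) by read length (18 to 28 nt) in total RNA, in FLAG precipitates and mocks, and in AGO6-antibody precipitates and mocks. Lines are group means and bars are SDs for groups of 2 libraries. The 24 nt peak is 48.3% in Col and 3.56% in pol4.

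**Figure D3:**
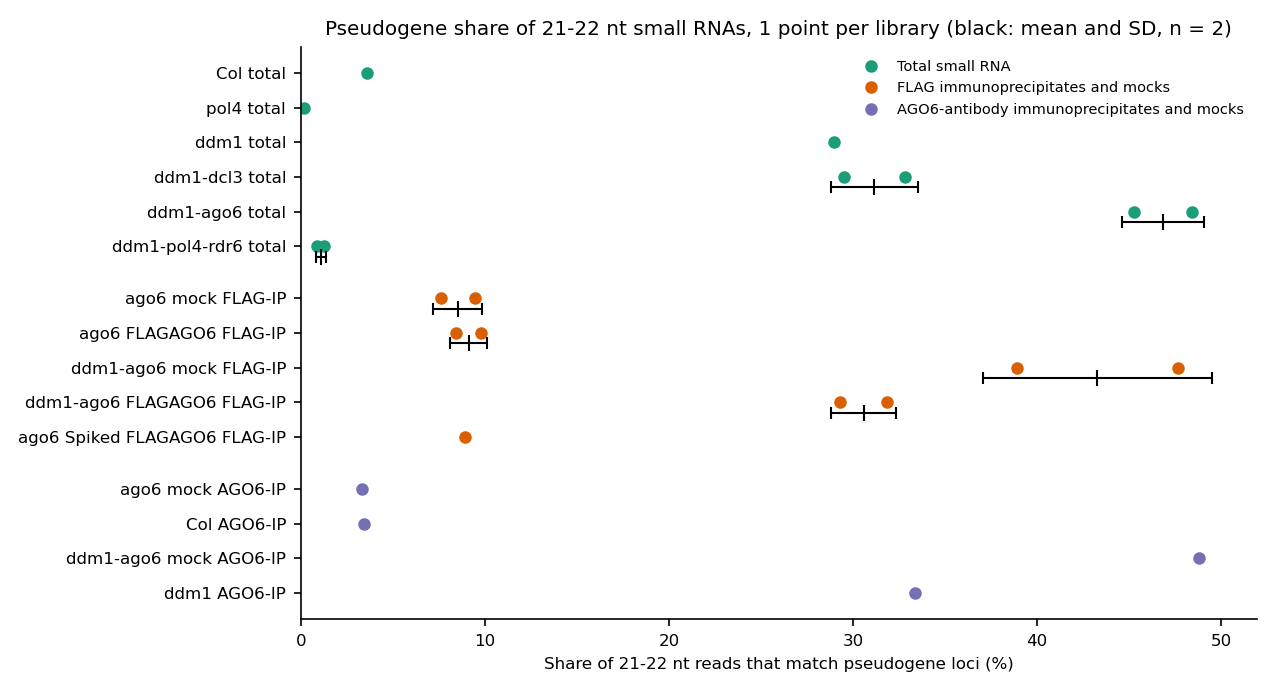
Share of 21 to 22 nt reads (%) that match pseudogene and TE gene loci, with 1 point per library and the mean and SD in black for groups of 2. The share is 3.59% in Col, 29% in ddm1 and 46.9% ± 2.23 in ddm1-ago6 total RNA.

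Loss of DDM1 alone was examined by setting the ddm1 library against the Col library, without a replicate check. The median log2 ratio of 204 pseudogene and TE gene loci was 3.12 for 21 to 22 nt RNAs (interval 2.67 to 3.46), above all 10000 random lists, and −1.31 for the 24 nt RNAs of 829 such loci. The 24 nt RNAs of 523 protein-coding genes had a median of −1.19, and the 57 MIR genes of the 21 to 22 nt class one of −0.10, which turned to 0.11 under miRNA scaling. The Copia retrotransposon EVD (AT5G17125, chromosome 5, 5630538 to 5634764) had 329 RPM of 21 to 22 nt RNA in ddm1 (Poisson interval 310 to 348) and no read in Col, at least 399-fold higher. AT5G32241 had 327 RPM in ddm1 and no read in Col, at least 397-fold higher. AT5G32228 (chromosome 5, 11846410 to 11848350) had 1140 RPM against 1.92 RPM, a log2 ratio of 8.88, and AT1G42370 had 417 RPM against 0.823 RPM (3 reads, 0.170 to 2.41), a log2 ratio of 8.30. The lowest ratios were those of 24 nt RNAs. AT2G04060 had none in ddm1 and 125 RPM in Col, at least 149-fold lower, and AT1G09485 had 1.68 RPM against 425 RPM (log2 −7.61). The 500000 bp bins dense in pseudogene loci held 46.9% of the 21 to 22 nt reads in ddm1 and 14.1% in Col.

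**Figure D4:**
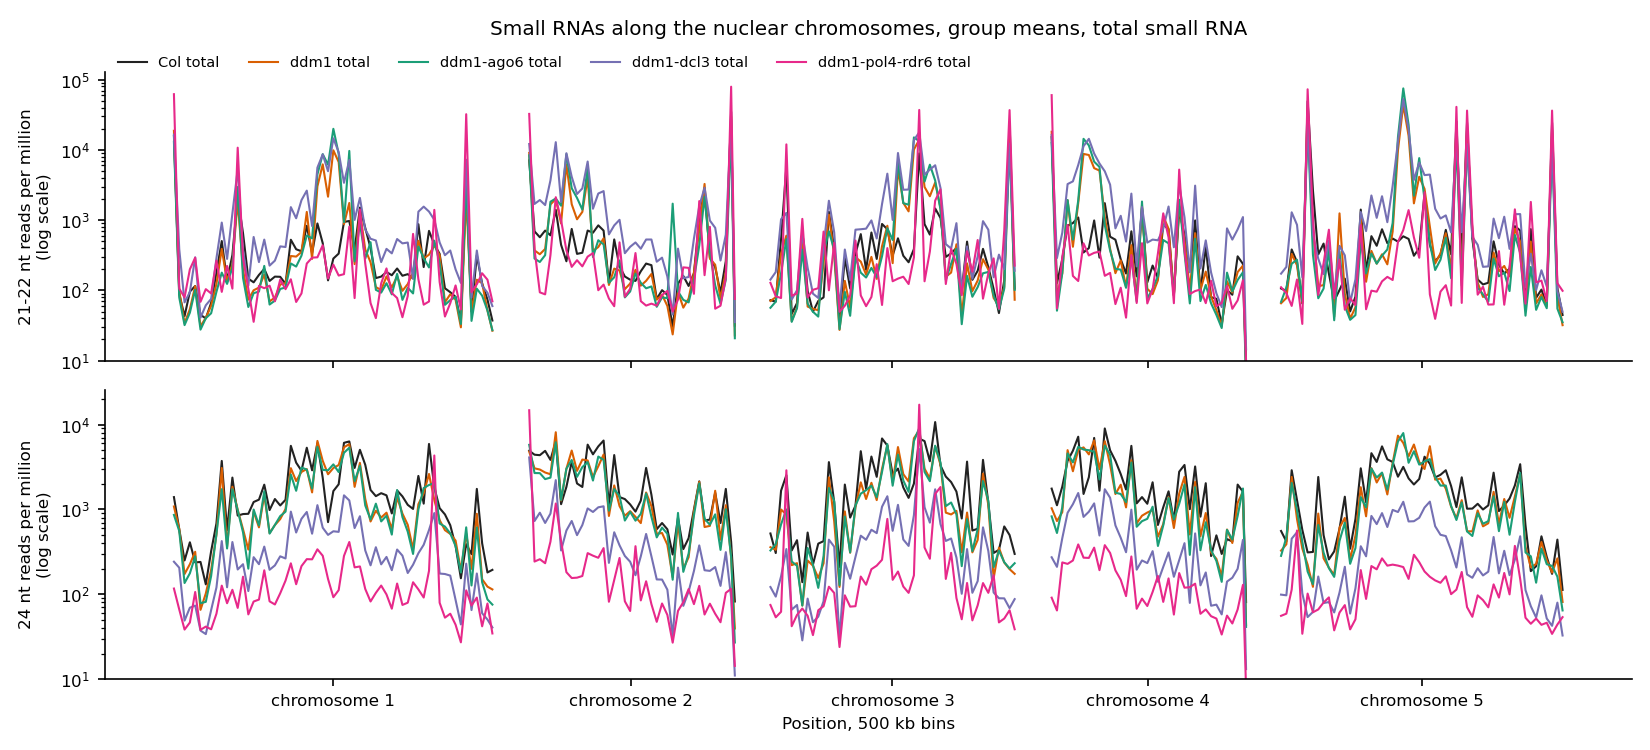
Group-mean small RNA (RPM, log scale) in bins of 500000 bp along chromosomes 1 to 5, for 21 to 22 nt (upper) and 24 nt (lower) reads of Col, ddm1, ddm1-ago6, ddm1-dcl3 and ddm1-pol4-rdr6 total RNA. The dense bins hold 14.1% of the 21 to 22 nt reads in Col and 46.9% in ddm1.

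The part of small RNA that depends on POL4 was examined by setting the pol4 library against Col. Of 625 pseudogene and TE gene loci, 624 had more than 2-fold less 24 nt RNA in pol4, with a median log2 ratio of −5.34. For protein-coding genes, 449 of 461 were lower in the same way, with a median of −5.44. The 24 nt RNAs of AT1G13760 went from 432 RPM to no read, at least 364-fold lower, and those of AT1G49260 (chromosome 1, 18225870 to 18226967) from 1378 to 1.58 RPM (log2 −9.37). The 21 to 22 nt RNA was also more than 2-fold lower, at 61 of 62 pseudogene and TE gene loci (median −5.10) and at 100 of 139 protein-coding genes (median −5.01), of which 32 rose more than 2-fold. In this class, 71 MIR genes had a median log2 ratio of 2.01 and 5 TAS loci one of 1.67, against 0.52 and 0.18 under miRNA scaling. The highest ratios were 24 nt RNAs of MIR genes, among them MIR319a at 134 RPM against 2.20 RPM and MIR160c at 21 RPM against no read, at least 25.5-fold higher.

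Whether DCL3 makes the small RNAs of active elements was examined by comparing ddm1-dcl3 with ddm1. The 24 nt RNAs of 896 of 2348 pseudogene and TE gene loci fell and those of 149 rose (946 and 184 when adjusted over the list alone), while 306 of 1127 rose and 16 fell in 21 to 22 nt RNA (277 and 13 when adjusted over the list alone). Protein-coding genes moved likewise, with 594 of 1665 lower in 24 nt RNA and 273 of 1607 higher in 21 to 22 nt RNA. The 21 to 22 nt RNA of AT5G35535 (chromosome 5, 13713460 to 13719312) rose from 9.53 to 1702 ± 237 RPM (SD, n = 2), a log2 fold change of 7.48 (SE 0.82, adjusted p = 7.25e-16). AT2G05820 rose from 1.40 to 205 ± 74.0 RPM (log2 7.17), and AT4G06536 from no read to 20.3 ± 1.25 RPM, at least 24.1-fold. The 24 nt RNA of AT4G08680, the AtMu1-like seed locus, rose from no read to 10.9 ± 7.50 RPM, at least 13-fold. The 10 lowest named units were all 24 nt. BNS (BONSAI, AT1G73177, chromosome 1, 27516572 to 27517882), a gene known to gain methylation in ddm1 lines, fell from 20.7 to 0.122 ± 0.172 RPM (log2 −7.09, SE 0.99, adjusted p = 4.16e-10). KAN2, a KANADI transcription factor of organ polarity, fell from 17.4 RPM to no read, at least 45.6-fold, and DDB1B from 16.5 RPM to no read, at least 43.4-fold. TAS1A, TAS1C and TAS2 fell in 24 nt RNA, with log2 fold changes of −2.31, −1.42 and −3.10, and no TAS locus was called in 21 to 22 nt RNA. Among mature sequences, miR159a rose from 2102 to 6660 ± 175 RPM, miR160, miR163 and miR173 also rose, and miR403 (log2 −2.60) and the TAS3 product tasiR-ARF (log2 −1.85) fell.

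In this comparison edgeR's quasi-likelihood test called 894 units higher and 1672 lower, 34.8% higher, with a median log2 fold change of 0.16 over all units. The share called higher was 46.7% and the median 0.54 under miRNA scaling, and DESeq2 called 843 units. The ddm1 group is a single library, so its own spread is taken from the other groups and its own deviation is not separated from the genotype.

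The role of AGO6 in the ddm1 background was examined by comparing ddm1-ago6 with ddm1. AGO6 itself rose from no 21 to 22 nt read to 1695 ± 229 RPM (n = 2), at least 2017-fold (adjusted p = 2.59e-26). In 21 to 22 nt RNA, pseudogene and TE gene loci rose more often than other loci, with 75 of 1127 higher and 10 lower (the same counts when adjusted over the list alone) against 13 of 2105 other loci higher (Fisher's exact test, adjusted p = 2.47e-21). Without ddm1-ago6 replicate A 39 of 1078 such loci were higher and without replicate B 35 of 1086, against 4 of 2061 and 10 of 2058 other loci. The ddm1 group is a single library, so these counts and tests do not separate the genotype from that library's own deviation. In 24 nt RNA, 165 of 2348 such loci rose and 56 fell (196 and 66 when adjusted over the list alone), with 62 and 6 without replicate A and 48 and 7 without replicate B. The 24 nt RNA of AT5G35935 (chromosome 5, 14083388 to 14089891) rose from no read to 78.4 ± 11.6 RPM, at least 93.2-fold, that of AT5G39205 from no read to 19.8 ± 0.198 RPM, at least 23.5-fold, and that of AT5G28085 from 0.280 to 45.8 ± 8.98 RPM (log2 7.22). Lower units included the 24 nt RNA of AT3G22955, which fell from 22.7 to 0.368 ± 0.245 RPM (log2 −5.93), and AT4G08370 in both size classes (log2 −5.06 in 21 to 22 nt and −4.67 in 24 nt RNA). Of mature sequences, tasiR-ARF fell from 93.3 to 28.8 ± 6.87 RPM (log2 −1.69, adjusted p = 0.0296) and miR403 by 1.5 on the log2 scale, and no TAS locus was called. Protein-coding genes had 81 higher and 96 lower units of 1665 in 24 nt RNA, a balance that turned to 118 higher and 47 lower under miRNA scaling and to 15 and 6 with DESeq2.

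The test called 350 units higher and 217 lower, 61.7% higher. This share was 87.9% under miRNA scaling, which moved the median log2 fold change from 0.16 to 0.78, and 88.6% with DESeq2, which called 105 units. Without ddm1-ago6 replicate A 179 units were called, and without replicate B 170.

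Loss of POL4 and RDR6 together was examined by comparing ddm1-pol4-rdr6 with ddm1. RNA of pseudogene and TE gene loci fell in both size classes: 589 of 1127 fell and 25 rose in 21 to 22 nt RNA, and 1271 of 2348 fell and 30 rose in 24 nt RNA (594 and 26, and 1278 and 32, when adjusted over the list alone). In 21 to 22 nt RNA they fell more often than other loci (adjusted p = 5.87e-84, Fisher's exact test), with 312 of 1089 lower without ddm1-pol4-rdr6 replicate A. The ddm1 group is a single library, whose own deviation these counts and tests do not separate from the genotype. The 21 to 22 nt RNA of AT4G06573 (chromosome 4, 3539458 to 3541365) fell from 355 RPM to no read, at least 943-fold, AT1G40310 from 222 RPM to no read, at least 591-fold, and AT1G42360 from 197 RPM to no read, at least 524-fold. All 5 TAS loci tested fell in both classes, from −4.49 (TAS1A) to −5.38 (TAS2) on the log2 scale in 21 to 22 nt RNA. TAS1C fell from 2329 to 63.7 ± 30.9 RPM (n = 2, log2 −5.21, adjusted p = 6.93e-20), and tasiR-ARF from 93.3 to 1.21 ± 1.05 RPM (log2 −6.78). The 21 to 22 nt RNA of RDR6 rose from 0.280 to 38.8 ± 2.93 RPM (log2 6.98, SE 1.14, adjusted p = 8.58e-09). That of the protein-coding genes RP1 (log2 5.18) and RCA (log2 4.59) rose too. Whether these reads are siRNAs or fragments of mRNA was not tested. Among miRNAs, miR159a rose from 2102 to 32020 ± 3643 RPM (log2 3.93) and miR160, miR163, miR165, miR167a, miR173, miR319a and miR390 rose by 1.75 (miR165) to 4.01 (miR163) on the log2 scale, while miR845b fell by 1.87. MIR genes had 51 higher and 16 lower of 162 in 21 to 22 nt RNA, which turned to 10 higher and 28 lower under miRNA scaling. Protein-coding genes had 261 higher and 304 lower of 1607, which turned to 723 and 171 with TMM factors.

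The test called 648 units higher and 3365 lower, 16.2% higher, with a median log2 fold change of −2.24. The share was 40.8% with TMM factors (median −0.85), 2.40% under miRNA scaling (median −3.36) and 3.57% with DESeq2, which called 2352 units. Without ddm1-pol4-rdr6 replicate A 2384 units were called.

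The replicated mutants of total RNA were compared with each other as well. Between ddm1-dcl3 and ddm1-ago6, pseudogene and TE gene loci were higher in 21 to 22 nt RNA at 430 loci and lower at 61 of 1127, and lower in 24 nt RNA at 1158 and higher at 145 of 2348 (427 and 61, and 1196 and 156, when adjusted over the list alone). In 21 to 22 nt RNA, AT2G05820 was at 205 ± 74.0 RPM in ddm1-dcl3 and 1.43 ± 0.0869 RPM in ddm1-ago6 (n = 2 each, log2 7.15, SE 0.62, adjusted p = 3.83e-27), and AT1G55260 at 147 ± 19.2 and 5.52 ± 3.11 RPM (log2 4.74). AGO6 had the lowest fitted log2 fold change of 21 to 22 nt RNA (−12.56), AT5G03620, a protein-coding gene, fell from 30.6 ± 5.01 RPM to no read, at least 80.5-fold, and BNS was lower in 24 nt RNA (log2 −6.86, adjusted p = 2.27e-11). TAS1A, TAS1C, TAS2 and TAS3 were lower in 24 nt RNA, with log2 fold changes of −1.71, −2.10, −2.36 and −1.59, and TAS1B was higher in 21 to 22 nt RNA (log2 1.12, adjusted p = 0.0323). Of mature sequences, miR173 was higher (log2 1.70, adjusted p = 0.00249) and miR403 lower (log2 −1.10, adjusted p = 0.0292), and 14 were not called. DESeq2 did not call TAS1B or miR403, and neither was called without ddm1-dcl3 replicate A or ddm1-ago6 replicate B, nor was TAS1B under miRNA scaling or without ddm1-ago6 replicate A, nor miR403 with TMM factors or without ddm1-dcl3 replicate B. Without either ddm1-ago6 replicate miR173 was not called. The test called 1317 units higher and 2151 lower, 38.0% higher against 24.4% of the 1318 that DESeq2 called, with a median log2 fold change of −0.22 (−0.46 under miRNA scaling). Without ddm1-ago6 replicate B 2179 units were called.

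Between ddm1-pol4-rdr6 and ddm1-ago6, 695 of 1127 pseudogene and TE gene loci were lower in 21 to 22 nt RNA and 48 higher (695 and 49 when adjusted over the list alone), and 1607 of 2348 were lower in 24 nt RNA. In 21 to 22 nt RNA, AT4G06573 fell from 382 ± 75.3 RPM to no read (n = 2 each), at least 1017-fold, AT5G34985 from 286 ± 36.8 RPM to no read, at least 759-fold, and AGO6 by 13.47 on the log2 scale. All 5 TAS loci fell in both classes, by 3.99 to 4.66 on the log2 scale in 21 to 22 nt RNA. RDR6 rose (log2 6.29, adjusted p = 1.34e-17), as did the 24 nt RNA of MIR319a, from 3.22 ± 2.07 to 91.6 ± 8.53 RPM (log2 4.79). Of mature sequences, 13 were called higher, most of all miR390 (log2 3.45, adjusted p = 3.85e-12), tasiR-ARF (log2 −5.09, adjusted p = 3.83e-12) and miR845b (log2 −1.78) fell, and miR172a was not called, while 7 of the 13 turned under miRNA scaling. MIR genes had 83 higher and 15 lower of 162, which turned to 14 and 38 under miRNA scaling. The test called 1064 units higher and 4021 lower, 20.9% higher with a median log2 fold change of −2.74. The share was 39.6% with TMM factors (median −1.58), 1.79% under miRNA scaling (median −4.28) and 4.77% with DESeq2, which called 3101 units, and 3035 units were called without ddm1-pol4-rdr6 replicate A.

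The small RNAs that AGO6 binds while transposable elements are silent were sought by comparing FLAGAGO6 precipitates with mocks in ago6. Few loci stood above the mock. The 24 nt RNA of CNGC13 (AT4G01010, chromosome 4, 434217 to 437605), a cyclic nucleotide gated channel gene, was at 19 ± 0.208 RPM (SD, n = 2) with no read in the mocks, at least 101-fold higher (adjusted p = 0.00222), and its 21 to 22 nt RNA at 13 ± 0.996 against 0.179 ± 0.253 RPM (log2 5.69, SE 1.04). AGL23 (AT1G65360, chromosome 1, 24281337 to 24282233), a MADS-box gene of the female gametophyte, had 28.4 ± 0.346 against 0.179 ± 0.253 RPM of 21 to 22 nt RNA (log2 6.81, SE 1.06, adjusted p = 0.00123). The non-coding RNA AT3G07775 had 27.2 ± 4.77 against 0.641 ± 0.611 RPM (log2 5.17, adjusted p = 0.000688), and the pseudogene AT4G13470 19.5 ± 10.6 against 0.104 ± 0.148 RPM (log2 7.84). The non-coding RNA AT2G01422 was lower in both classes (log2 −4.52 in 24 nt and −3.00 in 21 to 22 nt RNA). Protein-coding genes were higher at 26 of 2124 loci in 21 to 22 nt RNA (43 when adjusted over the list alone), more often than other loci (adjusted p = 0.000242, Fisher's exact test). Pseudogene and TE gene loci were higher at 2 of 2420 (2 when adjusted over the list alone), less often than other loci, of which 31 of 2734 were higher (adjusted p = 1.82e-05). No TAS locus or mature sequence was called, and TAS1C had 2599 ± 1150 RPM in the precipitates and 4749 ± 2230 RPM in the mocks. By replicate letter, TAS1C was at 1788 against 3172 RPM (A) and 3410 against 6326 RPM (B), a pairing that the test did not use. The first base of 24 nt reads was A in 69.4% ± 0.819 of the precipitates' reads and 69.0% ± 0.608 of the mocks'.

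The test called 53 units higher and 5 lower, against 216 called under miRNA scaling, which moved the median log2 fold change from −0.11 to 0.41. The count was 5 without ago6 mock replicate A, 8 without mock replicate B and 20 without FLAGAGO6 replicate B.

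The same comparison in ddm1-ago6 asked which small RNAs AGO6 binds once elements are transcribed. EVD was higher in the precipitates, with 14.9 ± 0.888 against 2.06 ± 0.997 RPM of 24 nt RNA (n = 2 each, log2 2.85, SE 0.68, adjusted p = 0.0155). COP1 had 66.3 ± 7.71 against 0.612 ± 0.386 RPM of 21 to 22 nt RNA (log2 6.76, SE 0.69, adjusted p = 2.29e-06) and AT1G49260 had 118 ± 21.3 against 12.2 ± 0.301 RPM (log2 3.27, SE 0.44, adjusted p = 5.92e-05). In total RNA, ddm1-ago6, the genotype of the mocks, had less 21 to 22 nt RNA of EVD and less 24 nt RNA of AT1G49260 than the single ddm1 library. The higher levels over mock thus do not separate binding to AGO6 from the RNA content of the plants. Lower units outnumbered higher units. The 21 to 22 nt RNA of AT5G32512 (chromosome 5, 12146025 to 12148775) was at 6.54 ± 0.658 RPM against 303 ± 227 RPM in the mocks (log2 −5.53, adjusted p = 4.37e-06), and the 24 nt RNA of AT4G01490 at 0.304 ± 0.43 against 15.3 ± 2.36 RPM (log2 −5.75). Pseudogene and TE gene loci were lower in the precipitates at 95 of 2420 and higher at 23 in 21 to 22 nt RNA, and lower at 153 of 2088 and higher at 5 in 24 nt RNA (103 and 24, and 209 and 7, when adjusted over the list alone). In both classes they were lower more often than other loci (adjusted p = 9.37e-14 and 1.1e-07, Fisher's exact test). Their share of 21 to 22 nt reads was 30.6% ± 1.78 in the precipitates and 43.3% ± 6.20 in the mocks. The first base was A in 69.2% ± 0.875 of 24 nt reads of the precipitates and 67.1% ± 1.08 of the mocks, and in 37.6% ± 2.35 and 30.5% ± 6.81 of 22 nt reads. For 21 nt reads outside MIR genes it was A in 30.1% ± 4.38 and 25.7% ± 0.589. The replicates did not overlap in these 3 shares, but an exact permutation test of 2 against 2 libraries cannot give a p under 0.333. In ago6 the replicates of precipitates and mocks overlapped in all 3. There A stood first in 38.8% ± 7.55 and 36.6% ± 1.01 of 22 nt reads, and in 36.3% ± 4.39 and 33.3% ± 0.833 of 21 nt reads outside MIR genes. No TAS locus or mature sequence was called.

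The test called 56 units higher and 317 lower, with a median log2 fold change of −0.38. With TMM factors, and with the replicate letter as a block, more units were called, by over 1.5 times. The count was 37 without FLAGAGO6 replicate A, 60 without FLAGAGO6 replicate B and 841 without mock replicate B.

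Whether the enrichment over mock differed between the backgrounds was tested as an interaction. EVD differed upwards, with more RNA over mock in ddm1-ago6 than in ago6 in both classes, with log2 differences of 3.79 (SE 0.78, adjusted p = 0.0134) in 21 to 22 nt RNA and 4.24 (adjusted p = 0.0488) in 24 nt RNA. Its 21 to 22 nt RNA was at 192 ± 16.9 RPM in the precipitates and 39.8 ± 2.90 RPM in the mocks of ddm1-ago6, against 1.25 and 3.15 RPM in ago6 (n = 2 each). In total RNA this EVD RNA was lower in ddm1-ago6, the genotype of the mocks, than in the single ddm1 library. The EVD difference therefore does not separate binding to AGO6 from the RNA content of the plants. In 21 to 22 nt RNA, COP1 (log2 5.75), AT2G12210 (log2 5.88) and AT1G36010 (log2 4.15) also differed upwards. AGL23 (log2 −12.39) and the 24 nt RNA of CNGC13 (log2 −12.06) differed downwards, as did the sucrose transporter gene SUC9 in 24 nt RNA (log2 −7.94). AGL23 and the 24 nt RNA of CNGC13 had groups without a read, so their fitted differences depend on the prior count and are not bounds. Of 1231 protein-coding genes in 24 nt RNA, 35 were lower and none higher, more often than other loci (51 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.0202), which became 14 of 1231 (adjusted p = 0.0398) after a rescaling that brought the median of the 24 nt units near 0. Of pseudogene and TE gene loci, 4 were higher and 26 lower in 21 to 22 nt RNA, and 1 was higher and 22 lower in 24 nt RNA. The test called 9 units higher and 112 lower, and no TAS locus or mature sequence, with a median log2 difference of −0.42 (−0.90 under miRNA scaling). After the rescaling of the 24 nt median it called 29 higher and 29 lower, so the balance of directions depends on the scaling. The count was 2 without ddm1-ago6 FLAGAGO6 replicate A, 22 without its replicate B, 67 without ago6 FLAGAGO6 replicate A, 39 without its replicate B, 4 without ago6 mock replicate A and 551 without ddm1-ago6 mock replicate B.

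The FLAGAGO6 precipitates of the backgrounds were also compared directly, a difference that includes their plants' total RNA. EVD had 192 ± 16.9 RPM of 21 to 22 nt RNA in ddm1-ago6 and 1.25 ± 1.24 RPM in ago6 (n = 2 each, log2 7.42, SE 0.66, adjusted p = 2.46e-08), and AT5G37610 (chromosome 5, 14938032 to 14938612) had 32.6 ± 0.723 against 0.181 ± 0.0783 RPM (log2 7.46). The pseudogene AT2G07590 had 102 ± 48.5 against 1.31 RPM (log2 6.41). The 24 nt RNA of AT3G42310 had no read in ddm1-ago6 and was at least 77.2-fold lower there than in ago6, and AGL23 went from 28.4 ± 0.346 RPM to no read, at least 72.9-fold lower. Among pseudogene and TE gene loci, units were called in both directions, 303 higher and 1067 lower of 2420 in 21 to 22 nt RNA (319 and 1125 when adjusted over the list alone), each more often than other loci (adjusted p = 7.2e-23 and 5.71e-39, Fisher's exact test). They made up 30.6% ± 1.78 of the 21 to 22 nt reads in ddm1-ago6 and 9.11% ± 0.985 in ago6. TAS1B (log2 −1.42, adjusted p = 0.0104) and miR172a (log2 −2.04, adjusted p = 0.0427) were lower, but TAS1B was not called with TMM factors, under miRNA scaling or with DESeq2, and miR172a turned to 0.28 without ago6 FLAGAGO6 replicate B. The test called 698 units higher and 3145 lower, 18.2% higher with a median log2 fold change of −1.35. The share was 39.4% with TMM factors (median −0.51), 38.1% under miRNA scaling (median −0.57) and 35.8% with DESeq2 (median −0.68), and 2214 units were called without ddm1-ago6 FLAGAGO6 replicate A.

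The spiked lysate asked whether ddm1 small RNA binds to FLAGAGO6 after lysis. EVD, at 329 RPM in ddm1 total RNA, had 1 read of 21 to 22 nt (0.422 RPM) in the spiked precipitate and 2.13 and 0.376 RPM in the unspiked precipitates. Pseudogene and TE gene loci held 8.90% of 21 to 22 nt reads in the spiked precipitate (Wilson interval 8.85 to 8.96) and 9.11% ± 0.985 in the unspiked precipitates. TAS1C had 4455 RPM against 2599 ± 1150 RPM (n = 2) and miR159a 9087 against 8576 ± 192 RPM. No unit was called by edgeR's test, with 119 at an unadjusted p under 0.05, and DESeq2 called 0 as well, with 74. In simulated counts for this comparison 22% of 8-fold and 50% of 16-fold changes were recovered, so smaller changes were mostly not detectable. With the replicate letter as a block some units were called, as given below with the other settings.

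Native AGO6 was examined with an antibody, 1 library per genotype and no replicate check. In Col against the ago6 mock, AGL23 had 188 reads of 21 to 22 nt against 0 reads, at least 58.7-fold higher, and CNGC13 had 11.2 against 0.0701 RPM of 21 to 22 nt RNA (171 reads against 1, interval of the lower level 0.00178 to 0.391 RPM, log2 4.36) and 6.44 RPM of 24 nt RNA against no read, at least 30.6-fold higher. AT3G07775 had 15.2 against 0.140 RPM of 24 nt RNA (0.0170 to 0.507, log2 4.61) and 18.6 against 0.421 RPM of 21 to 22 nt RNA (log2 4.37). The 21 to 22 nt units of these 3 genes and the 24 nt unit of CNGC13 are also among the named units of the FLAGAGO6 precipitates of ago6, and the 24 nt unit of AT3G07775 is not. The median log2 ratio was −0.01 for the 21 to 22 nt RNA of 1004 pseudogene and TE gene loci (0.07 under miRNA scaling), below all 10000 random lists, and 0.51 for the 24 nt RNA of 341 protein-coding genes, above all of them. It was 0.71 for the 21 to 22 nt RNA of 45 rRNA, tRNA, snRNA and snoRNA genes, also above all random lists. For the 24 nt RNA of 19 such genes it was 0.57, within the range that held most random lists. Structural RNA of 21 to 22 nt was thus higher in the precipitate too, in a pair of single libraries without a test. In ddm1 against the ddm1-ago6 mock, the EVD-like locus AT1G34967 had 16.2 against 0.372 RPM (1 read, 0.00942 to 2.07, log2 4.26), the highest ratio, and AGO6 itself the lowest (log2 −11.70). The median of 553 pseudogene and TE gene loci in 21 to 22 nt RNA was 0.18, which turned to −0.25 under miRNA scaling. Between the ddm1 and Col precipitates, EVD was at 586 against 0.526 RPM (log2 9.16) and AT5G32228 at 1815 against 3.55 RPM (log2 8.81), while the median of 1142 such loci was −1.38. Pseudogene and TE gene loci held 33.4% of 21 to 22 nt reads in the ddm1 precipitate, 48.8% in the ddm1-ago6 mock (48.7 to 48.9), 3.43% in the Col precipitate (3.42 to 3.44) and 3.33% in the ago6 mock (3.32 to 3.34).

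In the authors' deposited tables, the 21 to 22 nt ratio was above 0 in 7.10% of pseudogene tiles for the antibody in Col and 10.7% in ddm1, and in 14.2 and 16.2% in the tables for FLAG in Col and 14.6 and 14.8% in those for FLAG in ddm1. These ratios carry no replicate error, and how the authors computed them is not stated. In each of the authors' deposited tables, the median 21 to 22 nt ratio of the pseudogene tiles above 0 was 1, as was that of the Athila-like tiles. A tile above 0 therefore need not have a ratio above 1, and these percentages do not count enriched tiles. Tiles of protein-coding genes were above 0 in 0.305 to 0.671% of cases in the authors' deposited tables. In Athila-like tiles, the authors' deposited tables have 44.2% above 0 for the antibody in Col and 24.8% in ddm1, and 30.3 and 39.3% for FLAG in Col and 18.3 and 15.7% in ddm1. The Athila-like set has 12 loci and held few of the reads counted here. It had 0.0518% ± 0.00676 of 21 to 22 nt reads in FLAGAGO6 precipitates of ago6 and 0.0226% ± 0.00165 in those of ddm1-ago6. The percentages describe this set and not Athila elements at large.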

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

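The tests of reads shared between loci, of carry-over between plants, of the ago6 allele and of loss of DDM1, of the 23 nt reads, of scaling and of the RNA content of the mock plants were chosen only after the result was seen.

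The interaction of FLAGAGO6 and the ddm1 background gave 121 units whose enrichment over mock differed between ddm1-ago6 and ago6. Those named as higher were AT2G12210 (log2 difference 5.88), COP1 (5.75), AT1G36010 (4.15), the non-coding RNA AT2G01422 (3.96) and EVD, AT5G17125, with 3.79 in 21 to 22 nt and 4.24 in 24 nt RNA. Those named as lower were AGL23 (−12.39), AT4G13470 (−8.61) and AT4G18150 (−7.52) in 21 to 22 nt RNA, and CNGC13 (−12.06), AT1G56630 (−11.28), AT2G44925 (−9.52), AT3G24542 (−9.11), the spliceosomal RNA gene U2.4 (−8.95), AT1G64035 (−7.95) and SUC9 (−7.94) in 24 nt RNA. The share of 23 nt reads, a length that no comparison of the report used, was 5.22 percentage points higher in FLAGAGO6 precipitates than in mocks of ago6 (25.8% ± 0.302 against 20.6% ± 3.07, n = 2 each). In ddm1-ago6 it was 5.39 points higher (20.7% ± 0.00534 against 15.3% ± 5.42, n = 2 each). Relative to 24 nt reads the direction was not the same in every pair. That ratio was 1.41 in the ago6 precipitate and 1.87 in the mock of replicate A, but 1.83 and 1.02 in replicate B.

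For the 112 lower units, scaling stays possible as a source of part of the calls, since 112 were still called lower with TMM factors and under miRNA scaling, which left the overall median at −0.40 or lowered it to −0.90, but 29 after a rescaling that moved the median of the 24 nt units from −0.92 to −0.06, and the median of the 112 went from −5.58 (quartiles −7.41 and −4.14) to −4.71 (−7.08 and −3.23), with adjusted p up to 0.217 and calls of 29 higher units against 9 before. Their median log2 difference between precipitate and mock was 1.75 in ago6 and −3.61 in ddm1-ago6. The mock plants lack AGO6, and total RNA of ddm1-ago6 against the single ddm1 library, tested for 100 of the units, had a median log2 fold change of 1.98, against 0.16 for the other 7683 units. A candidate explanation is that part of these RNAs accumulate in plants without AGO6 and enter the mock as background. The units were, however, picked in part for high levels in ddm1-ago6 mocks. Their higher level in total RNA of the same genotype therefore cannot tell the lack of AGO6 from other differences between these plants and the ddm1 library. The 24 nt units, with a median of 0.95 over 66, leave room for other sources, and 66 of the 112 units were called in ddm1-ago6 against 23 in ago6.

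Small RNAs of AGO6 itself in ddm1-ago6, and of COP1 only in the FLAGAGO6 precipitates of that background, were weighed as a second pattern. Reads shared with other loci are argued against, since 100% of the 21 to 22 nt reads with any match in AGO6 in ddm1-ago6 total RNA, counted or left out, matched the genome once. Carry-over from the transgenic plants is argued against too, since the lowest level without the transgene was 7.47 times the highest with it. The ago6 allele without loss of DDM1 and loss of DDM1 without the ago6 allele are each argued against, since the lowest ddm1-ago6 level was 21.8 times the highest of the 6 ago6 libraries and 194 times the highest of the other 6 that lack DDM1, and the combination stays open, as untested. For COP1, 98.8% of 505 reads lay in the part of the gene next to AGO6, so that a transgene that carries this end of COP1 may be the source. The position of the reads alone does not single out the transgene. The FLAGAGO6 precipitates of ago6 had 0 to 0.502 RPM of COP1, which argues against the transgene without loss of DDM1 as the source.

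The 23 nt reads were the third pattern. They made up 11.5 to 26% of the FLAG precipitates and mocks, 3.24 to 5.72% of the antibody libraries and 5.29 to 8.13% of Col, ddm1 and ddm1-ago6 total RNA. Relative to 24 nt reads the antibody libraries stood above total RNA too. The ratio of 23 to 24 nt reads was 1.02 to 1.87 in FLAG libraries, 0.657 to 0.969 in antibody libraries and 0.147 to 0.169 in that total RNA. Shortened 24 nt RNAs stay possible as a source, but the overlap of sequences cannot decide it. In FLAG libraries, 44.1 to 56.6% of 23 nt reads with a single match were a 24 nt sequence of the library less a base at 1 end. The overlap was larger in Col, ddm1 and ddm1-ago6 total RNA, where 23 nt reads were fewer. Less the last base it was 47.0 to 55.9% there and 29.4 to 39.8% in FLAG libraries. Less the first base it was 58.0 to 67.3% and 31.8 to 45%. Loss of the last base of every small RNA during library making is argued against as the whole source. The median share of mature miRNA reads without their last base was at most 0.282 times the share of 23 nt among 23 and 24 nt reads. That miRNA share was 10.1 to 18.1% in FLAG libraries and 7.21 to 12.9% in antibody libraries. In Col, ddm1 and ddm1-ago6 total RNA it was 3.53 to 4.85%, so such loss stays possible for part of the 23 nt reads. Binding to FLAGAGO6 is argued against as the whole source, since the lowest share in a FLAG mock was 1.41 times the highest in total RNA of Col, ddm1 and ddm1-ago6.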

How the results depend on the processing

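Dividing reads over all matches and, for the interaction, the rescaling that brings the median of the 24 nt units near 0 were chosen after the data were seen, and the other alternatives were fixed beforehand. The counts of called units came out within 1.5 times of the reported count with sequences of a single match in all 10 comparisons, and in the settings and comparisons not named below. The single-match setting placed nearly the same share of reads as the reported rule. It therefore cannot show how reads shared between loci affect the counts. Dividing reads over all matches does use such reads, and the counts it moved are given below. Where a count or value moved, the cause was not tested. With TMM factors the count was 124 for FLAGAGO6 over mock in ago6, 576 in ddm1-ago6 and 227 for the interaction. Under miRNA scaling it was 216 in ago6 and 294 for the interaction, and it was 58 for the interaction with the 24 nt median brought near 0, where 14 of the 16 named units stayed called. DESeq2 called 843 units in ddm1-dcl3 against ddm1, 105 in ddm1-ago6 against ddm1, 2352 in ddm1-pol4-rdr6 against ddm1, and 1318 and 3101 in ddm1-dcl3 and ddm1-pol4-rdr6 against ddm1-ago6. Without the low-count filter 107 units were called in ago6, 1575 in ddm1-dcl3 and 291 in ddm1-ago6 against ddm1. With reads divided over all matches the counts were 4240 and 1013 in ddm1-dcl3 and ddm1-ago6 against ddm1, and 5279 in ddm1-dcl3 against ddm1-ago6.

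Over all units the replicate letters do not pair the samples, since the correlations of same-lettered deviations lay between −0.0736 and 0.148. That does not hold for every set of RNAs. In ago6, the 21 to 22 nt RNA of TAS1A, TAS1B, TAS1C, TAS2 and TAS3 was higher in B than in A, in precipitates and mocks alike. Some mature sequences shifted with the letter too, and miR165 was higher in A in both. The reported test does not pair the letters and counts such shifts as spread between replicates. In ago6, miR319a was at 1597 (A) and 6199 RPM (B) in the precipitates and 2661 and 8494 RPM in the mocks. For miR156 the levels were 571 and 202 RPM against 457 and 482 RPM, without a shared shift. With the replicate block the count was 153 in ago6, 561 in ddm1-ago6, 251 for the interaction, 13 for the spiked lysate and 332 for ddm1-ago6 against ddm1, and it changed no other count by over 1.5 times.

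With each replicate left out in turn, the count ran from 5 to 39 for FLAGAGO6 over mock in ago6, from 37 to 841 in ddm1-ago6, from 2 to 551 for the interaction, from 2214 to 3029 between the precipitates and stayed at 0 for the spiked lysate. The lowest counts came without ago6 mock replicate A (5), without ddm1-ago6 FLAGAGO6 replicate A (37, 2 and 2214) and the highest, 841 and 551, without ddm1-ago6 mock replicate B. In total RNA it ran from 1802 to 2198 for ddm1-dcl3, 170 to 179 for ddm1-ago6 and 2384 to 3730 for ddm1-pol4-rdr6 against ddm1, and from 2179 to 2975 and from 3035 to 4683 for ddm1-dcl3 and ddm1-pol4-rdr6 against ddm1-ago6. A replicate left alone was assumed to vary like the other groups. Of the named units' values in these fits, 659 kept direction and call, 154 kept direction only and 1 turned: miR172a between the precipitates, which ran from −2.87 to 0.28, the latter without ago6 FLAGAGO6 replicate B.

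Named units kept their direction in all 233 cases with TMM factors (11 no longer called), DESeq2 (35), no filter (18), divided reads (5), the replicate block (9) and single matches (0). For single matches this carries little weight, since nearly the same share of reads was placed. Under miRNA scaling 16 were no longer called and 7 turned in ddm1-pol4-rdr6 against ddm1-ago6: miR156 (−0.60), miR161.1 (−0.39), miR166 (−0.15), miR167a (−0.61), miR168 (−0.38), miR319a (−0.27) and miR403 (−0.75).

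Among medians of single libraries whose interval excluded 0, miRNA scaling turned the 21 to 22 nt RNA of other non-coding RNAs in ddm1 against Col (0.00076), of rRNA, tRNA, snRNA and snoRNA genes in pol4 against Col (−0.47) and the 24 nt RNA of TAS loci there (−0.59). It also turned those of pseudogene and TE gene loci (−0.25), protein-coding genes (−0.0131) and rRNA, tRNA, snRNA and snoRNA genes (−0.22) in the ddm1 antibody precipitate against mock, and of TAS loci against Col (0.30). Of medians whose interval included 0, it changed the sign of 5: MIR genes in 21 to 22 nt RNA of ddm1 against Col (0.11), rRNA, tRNA, snRNA and snoRNA genes in 24 nt RNA of pol4 against Col (−1.09) and in 21 to 22 nt RNA of the ddm1 against the Col precipitate (0.73), and, in the Col precipitate against mock, pseudogene and TE gene loci in 21 to 22 nt RNA (0.07) and TAS loci in 24 nt RNA (0.03). The 24 nt median of pseudogene and TE gene loci in pol4 against Col was −7.21 under miRNA scaling, −7.27 with 0.1 RPM added and −3.66 with 2 RPM added. The 21 to 22 nt median of these loci in ddm1 against Col was 2.54 with 2 RPM added, and the 24 nt median in the Col precipitate against mock 0.29 under miRNA scaling.

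Of the size and base shares, 23 moved by more than 1 SD or their interval and 7 did not with 20 to 25 nt reads as the denominator, 42 and 3 with each distinct sequence counted once, and 40 and 5 with single matches. The share of 24 nt reads that start with A cannot change with that denominator, so no value is given. Depth limits single units: 3 reads correspond to 0.172 to 1.94 RPM.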

Other observations

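No hypothesis was tested in this part, and the values were picked after the data were seen.

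The protein-coding locus AT1G49260 gave abundant siRNAs, which were higher in AGO6 precipitates than in their mocks. Its 24 nt RNA was at 1378 RPM in Col, 193 RPM in ddm1 and 36.7 and 23.7 RPM in the ddm1-ago6 total RNA. Its 21 to 22 nt RNA was at 712 and 537 RPM in the FLAGAGO6 precipitates of ago6 and 75.1 and 38.0 RPM in the mocks, and at 102 and 132 RPM against 11.9 and 12.4 RPM in ddm1-ago6. With the AGO6 antibody it was at 235 RPM in Col and 26.1 RPM in the ago6 mock. The mock plants lack AGO6, and no total RNA of ago6 or of the transgenic plants was among the libraries. Binding to AGO6 is therefore not separated from the RNA content of the plants.

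EVD siRNAs of 21 to 22 nt differed between the mutants of the ddm1 background, from 329 RPM in ddm1 to 95.3 and 60.0 RPM in ddm1-dcl3, 79.3 and 119 RPM in ddm1-ago6 and 44.1 and 46 RPM in ddm1-pol4-rdr6. The EVD-like loci held 0.442% of the 21 to 22 nt reads in ddm1 and 0.0999% ± 0.0185 (n = 2) in ddm1-ago6. The first base of 24 nt reads was A in 62.2% of Col, 62.1% of ddm1 and 59.9% ± 1.57 of ddm1-ago6 total RNA, and in 52.6% ± 2.97 of ddm1-dcl3 and 41.1% ± 5.53 of ddm1-pol4-rdr6. In ddm1-dcl3 it was G in 22.8% ± 3.85, against 10.6% in ddm1. In the antibody libraries A stood first in 49.5% of the 24 nt reads from Col and 48.4% of those from the ago6 mock.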
